A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

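The series holds 4 ChIP-exo libraries from Saccharomyces cerevisiae, 1 each from strains with TAP-tagged Xrn1, Dcp2 or Lsm1 and 1 from a strain without a TAP tag. Per the labels' protocols, cells were fixed with 1% formaldehyde, chromatin was sheared by 30 cycles of sonication to a median of 250 to 300 bp, complexes were pulled down on IgG beads, and DNA on the beads was digested with lambda and RecJf exonucleases before the second adaptor was ligated. Per the file headers, the deposited values are counts of tags per position on the forward strand, on the reverse strand and their sum, with no normalization. That a count is of 5′ ends is the usual content of such tables and is not stated. The aligner, genome build, filters and handling of duplicates are not given in the sources used here. The series text speaks of 2 replicates of each experiment; whether each file sums both is not given either, so each file was treated as 1 library. All 4 files matched a sample, and 0 were left unmatched.

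Because no build was named, the positions were first tested against the gene table of the R64 assembly. For each chromosome the gene table was moved in steps of 10 bp over 1000 bp in both directions, and the lag that put most positions just upstream of start codons was taken. On 15 of 16 chromosomes this lag was at most 10 bp, and for the left and right parts of those chromosomes taken apart at most 80 bp; on the 14 of them with at least 10 tRNA genes, the lag that centred positions on tRNA genes was at most 30 bp. On chromosome XI the lags were -370 and -360 bp, and this chromosome was left out of everything that uses genes. The gene table was thus used beyond names on the strength of this test alone, distances to genes may be off by up to 80 bp in places, and no R64 coordinates are given. Indices are printed as the files give them, their lowest being 0. The gene table holds 5684 coding genes on the chromosomes used, of which 96.3% have a coding length divisible by 3, so start codons and not transcription start sites were the anchors.

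Tables were processed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. For each coding gene, tags were summed in the 300 bp upstream of the start codon. A gene was called when its count exceeded the library's mean density over the nuclear genome without the ribosomal DNA repeat by a 1-sided Poisson test, with a Benjamini-Hochberg adjusted p of at most 0.05 over all genes; this tests a library against an even spread of its own tags, not conditions. Ratios between libraries have exact conditional binomial intervals and shares have Clopper-Pearson intervals, all at 95% and for counting error only. In the closing part, the ratios of upstream shares to no-TAP have 95% intervals from 10000 resamplings of 234 blocks of 50 kb. Where the control had 0 tags, a lower bound was taken from a floor of 3 tags, which is 89.8 CPM (tags scaled to the library total) in the no-TAP library and 19.0, 8.39 and 14.2 in Xrn1-TAP, Dcp2-TAP and Lsm1-TAP. Shares by feature were set beside 10000 circular shifts, overlaps of genes beside 1000, and list values beside 10000 random lists of the same size. Counting error alone between 2 libraries was drawn 20 times. With 1 library per group there is no p-value between conditions.

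The groups, tests, windows, 13 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, by upstream CPM, the 8 highest genes of each TAP library whose ratio to no-TAP had a lower bound above 1, the 8 genes with the best worst rank over the 3 TAP libraries, the 4 highest of no-TAP, the 3 tagged loci, and the 2 highest members of each list; genes in repeats are called uncertain. The alternatives fixed then were windows of 150 and 500 bp or ended at the neighbouring gene, positions with at least 2 tags, each position counted once, thinning to the no-TAP depth, median-ratio scaling, a filter of 10 tags over the 4 libraries, removal of the ribosomal DNA or of positions within 100 bp of a no-TAP position, and tandem genes only. Chosen after seeing the data were the leaving out of chromosome XI, proximity of single positions, thinning of positions, ratios of positions and of promoter folds to no-TAP, overlaps of positions counted once, start codons moved by 30 bp and lists without windows that hold an RNA gene. The TATA element comparison was not run, as no genome sequence was used here, and Ty elements, telomeres, centromeres, replication origins and mitochondrial DNA were not analysed here.

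The procedures were tested on simulated counts for the 5684 genes with 200 changed genes at a time. At the depth of positions, genes raised 8-fold were called in 26.0% of cases in Xrn1-TAP, 80.5% in Dcp2-TAP, 44.5% in Lsm1-TAP and 1.50% in no-TAP, and at the depth of tags in 100%, 100%, 100% and 75.5%. For ratios to no-TAP, an 8-fold change lay above 1 in 20.0%, 10.5% and 13.5% of cases by positions and in 79.0%, 82.5% and 74.5% by tags, for Xrn1-TAP, Dcp2-TAP and Lsm1-TAP. The simulated tags were independent draws, while the real tags lay 7.04 to 8.56 to a position on average. The simulated values by tags therefore do not show how the procedures perform on the real tags.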

Results

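Chromatin pulled down with 3 tagged cytoplasmic mRNA decay factors was sequenced from budding yeast grown in rich glucose medium. The factors were Xrn1, the 5′ to 3′ exonuclease that degrades decapped mRNA, Dcp2, the catalytic subunit of the decapping enzyme, and Lsm1, a subunit of the ring that binds the 3′ ends of deadenylated mRNAs and promotes decapping. Each carried a TAP tag, whose protein A part binds IgG, in its own strain, and an untagged (no-TAP) strain taken through the same IgG pull-down gave the background. The assay was ChIP-exo, in which an exonuclease trims each crosslinked DNA fragment back to the protein, so that the 5′ ends of the sequenced tags mark its borders. There was 1 library per strain, so no difference between strains has a replicate check. Every interval is an exact 95% interval that covers counting error only, apart from those over 50 kb blocks in the closing part. The Xrn1-TAP library held 158105 tags, Dcp2-TAP 357674, Lsm1-TAP 211236 and the no-TAP control 33412. These tags lay at 18481, 44955, 25342 and 4743 distinct positions (a position and strand counted once), with 8.56, 7.96, 8.34 and 7.04 tags per position on average. Since PCR copies of a fragment add tags at the same position, the tags are not independent molecules, and values from distinct positions stand beside those from tags below.

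The tagged strains gave more distinct positions than the untagged strain. Dcp2-TAP had 9.48 times as many positions as no-TAP (9.20 to 9.77), Lsm1-TAP 5.34 times (5.18 to 5.51) and Xrn1-TAP 3.90 times (3.77 to 4.02). When each TAP library was thinned to the tag total of the no-TAP library, 19836 positions were left for Dcp2-TAP, 14582 for Lsm1-TAP and 11984 for Xrn1-TAP, which is 4.18, 3.07 and 2.53 times the no-TAP number. The split between DNA strands was close to even in all 4 libraries, with 49.2% to 51.0% of tags on the forward strand. In the tagged libraries, reverse-strand positions lay most often 30 to 39 bp (Xrn1-TAP), 10 to 19 bp (Dcp2-TAP) and 20 to 29 bp (Lsm1-TAP) downstream of a forward-strand position. Pairs with the reverse position 10 to 49 bp downstream were 1.5 (1.38 to 1.64), 1.40 (1.35 to 1.45) and 1.46 (1.37 to 1.56) times as frequent as pairs in the opposite order. In the no-TAP control they were 1.81 (1.31 to 2.51) times as frequent, and the most frequent distance was 110 to 119 bp with 63 pairs. A position near several others enters several pairs, so the pairs are not independent and these intervals are too narrow.

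**Figure D1:**
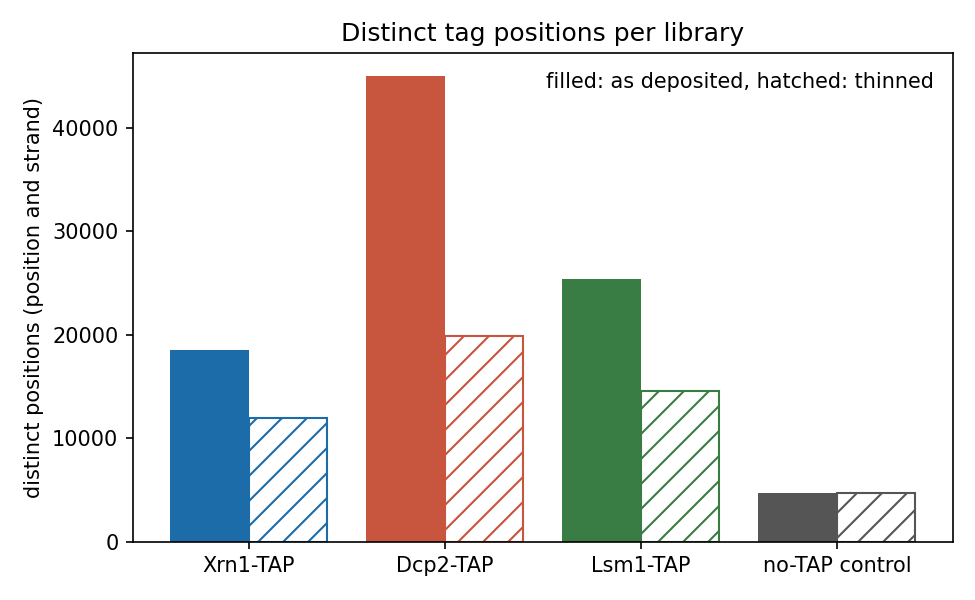
Distinct tag positions (y axis, number of positions) in the 4 libraries; filled bars show the deposited libraries and hatched bars the same libraries after random thinning to the 33412 tags of the no-TAP control. At equal tag number Dcp2-TAP keeps 19836 positions and the no-TAP control has 4743.

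The first question was where on the genome the tags of the decay factors lie. In all 4 libraries, the no-TAP control included, promoters and small RNA genes held more positions than their share of the genome, and coding regions held fewer. The 300 bp upstream of start codons make up 13.4% of the genome used and held 24.4% of the positions of Xrn1-TAP, 26.1% of Dcp2-TAP, 22.2% of Lsm1-TAP and 25.5% of no-TAP, a fold of 1.82 (1.77 to 1.87), 1.94 (1.91 to 1.98), 1.65 (1.61 to 1.69) and 1.90 (1.81 to 2.00). Counted in tags the folds were 1.93, 2.02, 1.73 and 2.01. Coding regions were at 0.650, 0.631, 0.686 and 0.644 of their share, and the 300 bp past stop codons, many of which face the promoter of a neighbour, at 1.5, 1.59, 1.44 and 1.58. None of 10000 circular shifts of the positions along their chromosomes gave as high an upstream share in any of the 4 libraries, the highest shift reaching a fold of 1.21.

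Set against the untagged strain, the upstream share of positions was 0.957 times that of no-TAP in Xrn1-TAP (0.897 to 1.02) and 1.02 times in Dcp2-TAP (0.963 to 1.09), both intervals holding 1. In Lsm1-TAP it was lower by more than counting error, at 0.869 times (0.816 to 0.927), with a higher share in coding regions (1.07 times, 1.02 to 1.12) and in the ribosomal DNA (1.17 times, 1.05 to 1.31). Between the tagged libraries, Dcp2-TAP had 1.18 times the upstream share of Lsm1-TAP (1.14 to 1.22) and 0.786 times its ribosomal DNA share (0.745 to 0.829).

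**Figure D2:**
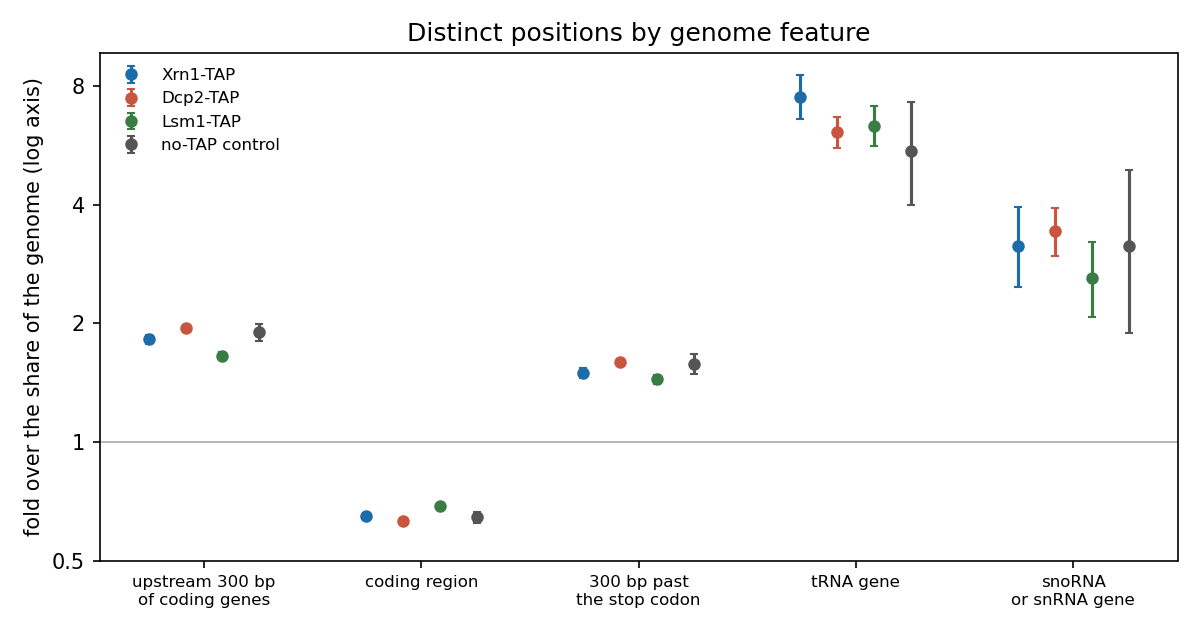
Fold of distinct positions over the share of the genome (y axis, log scale) in 5 kinds of genome feature for the 4 libraries; points are the folds and bars their exact 95% binomial intervals, which cover counting error only. Upstream windows lie between 1.65 and 1.94 in all 4 libraries, and tRNA genes between 5.47 and 7.52.

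Around start codons, the positions of all 4 libraries were most frequent in the promoter. The fullest 20 bp bin began 100 bp upstream of the start codon in the 3 tagged libraries and 80 bp upstream in the no-TAP control. Tags 41 to 140 bp upstream were 2.84 times (Xrn1-TAP), 3.07 times (Dcp2-TAP), 2.23 times (Lsm1-TAP) and 3.32 times (no-TAP) as dense as those more than 100 bp into the gene. With distinct positions in place of tags the folds were 2.75 (2.59 to 2.91), 3.17 (3.06 to 3.29), 2.25 (2.13 to 2.36) and 2.69 (2.40 to 3.01). Set against no-TAP, these position folds were 1.02 (0.900 to 1.16), 1.18 (1.05 to 1.33) and 0.836 (0.738 to 0.947) times as high, while by tags all 3 tagged libraries lay below no-TAP. The median tag lay 14, 13, 60 and 0 bp downstream of the nearest start codon, with quartiles of -248 and 673 bp in Xrn1-TAP, -241 and 661 bp in Dcp2-TAP, -247 and 712 bp in Lsm1-TAP and -241 and 657 bp in no-TAP. Past stop codons, positions 100 to 300 bp downstream were 2.03 (1.92 to 2.14), 2.27 (2.20 to 2.35), 2.00 (1.91 to 2.09) and 2.15 (1.93 to 2.39) times as dense as inside the gene. Around start and stop codons a position near several genes counts once for each gene, so the intervals of these folds and of their ratios are too narrow.

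The genes of small stable RNAs were among the densest features. The 259 tRNA genes, transcribed by RNA polymerase III, with 50 bp on each side held 5.12 (4.59 to 5.69), 4.89 (4.56 to 5.25), 5.35 (4.89 to 5.85) and 4.10 (3.20 to 5.19) times the positions that an even spread gives in Xrn1-TAP, Dcp2-TAP, Lsm1-TAP and no-TAP. The 71 snoRNA genes, whose products guide rRNA modification and processing, held 4.95 (4.16 to 5.83), 5.52 (4.99 to 6.10), 4.27 (3.64 to 4.97) and 5.04 (3.55 to 6.95) times that number. Within tRNA genes alone Xrn1-TAP had 1.38 times the share of the no-TAP control, with an interval of 0.997 to 1.94. The size of the excess depends on the unit. Within tRNA genes the folds over the share of the genome were 7.52, 6.11, 6.36 and 5.47 by positions but 3.39, 2.72, 2.73 and 2.65 by tags. Within snoRNA and snRNA genes the folds by tags were 2.75, 4.03, 2.73 and 3.37. SNR17A, a gene for the U3 snoRNA, had 11, 36, 11 and 3 positions, SNR30 had 11, 33, 14 and 2, and LSR1, the U2 snRNA gene, had 12, 21, 9 and 1. SNR45 had 9, 29 and 9 positions in the tagged libraries and 0 in the control, where an even spread gives 0.0996. These 4 genes were chosen after their values were seen. For snoRNA and snRNA genes without the flanks, between 98.3% and 99.8% of circular shifts lay below the observed folds of 3.15, 3.42, 2.60 and 3.15, the highest shift of each library lying above them.

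**Figure D3:**
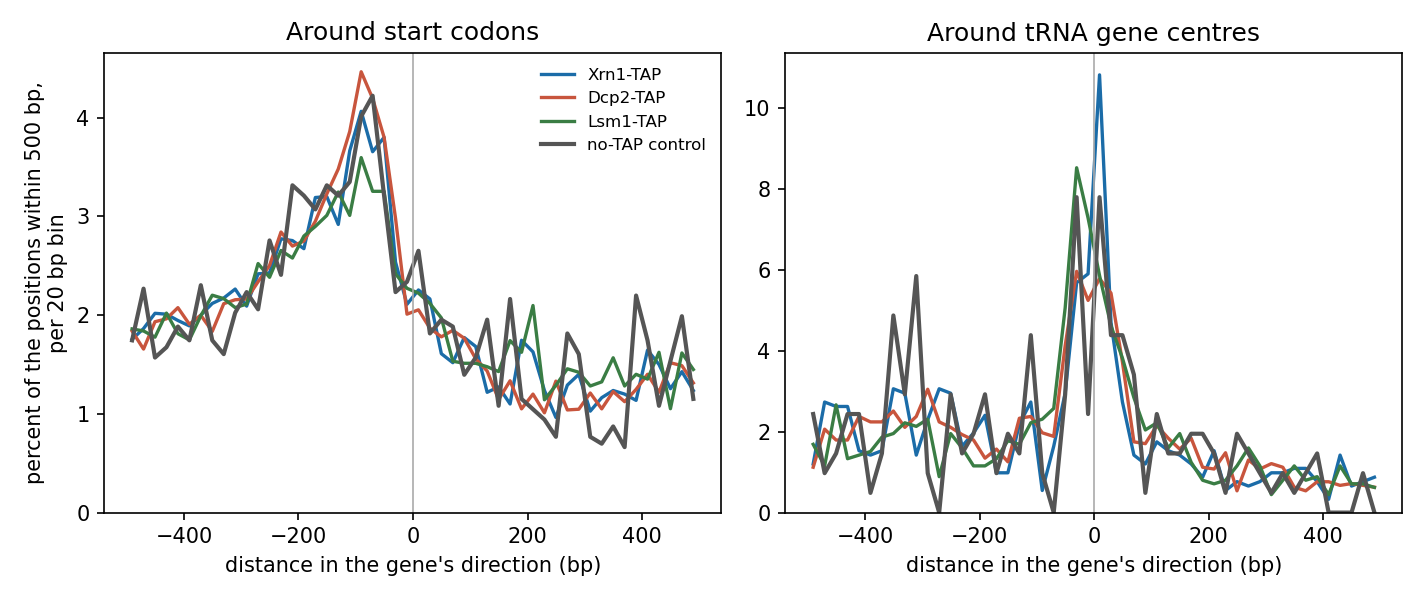
Distinct positions around start codons and around tRNA gene centres (x axis, distance in bp along the gene's direction; y axis, percent of a library's positions within 500 bp, per 20 bp bin); lines are the 4 libraries. All 4 lines peak upstream of the start codon and over the tRNA gene, the no-TAP line being the noisiest, with 2866 positions around start codons and 205 around tRNA genes. A position near several genes counts once for each gene.

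The next question was at which genes the factors lie. The genes with the highest upstream signal in all 3 tagged libraries included FAS2, the alpha subunit of fatty acid synthase, CPT1 and CDS1, enzymes of phospholipid synthesis, and CCW12, a cell wall mannoprotein whose window overlaps that of the dubious reading frame YLR111W. FAS2 had 11, 22 and 12 positions in Xrn1-TAP, Dcp2-TAP and Lsm1-TAP, CPT1 had 8, 22 and 16, CDS1 had 12, 20 and 15, and CCW12 had 15, 39 and 14. The no-TAP control had 6 positions at FAS2, 3 at CPT1, 4 at CDS1 and 5 at CCW12, against a mean of 0.229 per window. Scaled to library totals, the tags at CPT1 were 0.637 (0.476 to 0.864), 0.438 (0.332 to 0.586) and 0.398 (0.295 to 0.543) times those of no-TAP, and at CCW12 0.423 (0.327 to 0.549), 0.276 (0.217 to 0.354) and 0.251 (0.192 to 0.329) times. With tags scaled to the median ratio over genes, which raises the log2 ratios by 0.82, 0.89 and 1.39, CCW12 stays below no-TAP, while CPT1 turns above it in Xrn1-TAP and Lsm1-TAP with intervals that hold 1. By distinct positions, scaled to each library's total of positions, every interval held 1 for both genes. CPT1 then stood at 0.684 (0.164 to 4.01), 0.774 (0.232 to 4.04) and 0.998 (0.286 to 5.35), and CCW12 at 0.770 (0.266 to 2.71), 0.823 (0.324 to 2.68) and 0.524 (0.178 to 1.86). FAR8, which acts in recovery from pheromone arrest, had 6, 11, 8 and 1 positions. TAR1 and YLR154C-G also ranked among the highest, but they lie inside the ribosomal DNA repeat and are uncertain. The highest genes of the no-TAP control were CCW12 with 92 tags, GAS1, a cell wall glucanosyltransferase, with 81, and KEL2, a cell polarity protein, with 68. At GAS1 the tagged libraries had 0, 56 and 25 tags.

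By tags, 1621 of 5684 coding genes exceeded an even spread of the library's own tags in Xrn1-TAP, 2196 in Dcp2-TAP, 1621 in Lsm1-TAP and 638 in no-TAP (1-sided Poisson test, Benjamini-Hochberg adjusted p at most 0.05). That test takes tags as independent, and with each position counted once the numbers were 260, 626, 342 and 44. The numbers also follow depth, since thinned to the no-TAP number of positions the tagged libraries gave 47, 53 and 34 genes beside the 44 of the control. The loci of the tagged factors themselves held few positions: XRN1 had 1, 0, 2 and 0, DCP2 had 1, 3, 0 and 0, and LSM1 had 0, 1, 2 and 0. The mean window held 0.865, 2.25, 1.07 and 0.229 positions, so each locus lay somewhat above the mean in its own library, at 1 to 3 positions. XRN1, whose window overlaps that of NUP49, also lay above the mean in Lsm1-TAP, and DCP2 in Xrn1-TAP. Such values are therefore not particular to a library's own locus. By tags, LSM1 was called in Lsm1-TAP, with 20 tags at its 2 positions, and the other loci were called in no library.

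Gene by gene, the tagged libraries were then set against the untagged strain by tags in the upstream window, scaled to library totals. In Xrn1-TAP, the highest genes above no-TAP were RPL9B, a ribosomal protein of the large subunit, ZEO1, NOC4, a factor of small ribosomal subunit assembly, CUE5, AHP1, a thiol peroxidase, TEF1, translation elongation factor 1 alpha, CTH1, a zinc finger protein of mRNA turnover, and YLR154C-G. RPL9B stood at 3.20 times no-TAP (1.57 to 7.57), ZEO1 at 1.83 times (1.05 to 3.44), CUE5, whose window holds the snoRNA gene SNR9, at 2.77 times (1.36 to 6.59), TEF1 at 10.9 times (2.94 to 91.1) and NOC4 at 22.6 times (3.97 to 901). By distinct positions the ratios were smaller and every interval held 1. RPL9B stood at 1.54 (0.343 to 14.2) and ZEO1 at 1.03 (0.277 to 5.67), and CUE5, TEF1 and NOC4, with 8 positions against 1, at 2.05 each (0.275 to 91.1). AHP1 was at least 7.33-fold higher by tags and CTH1 at least 6.83-fold higher when the control, at 0 tags, is set to a floor of 3 tags per library, and the exact lower bounds of their ratios were 5.85 and 5.45. By positions these lower bounds were 0.370 and 0.235. The windows of RPL9B, CTH1, NDD1, CDS1, FAR8 and YDR524C-B overlap those of neighbouring genes.

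In Dcp2-TAP the leading genes were FAS2, AAR2, a splicing factor, TRX1, cytosolic thioredoxin, PDC1, the main pyruvate decarboxylase, YDR524C-B, YJL047C-A, whose window holds the snoRNA gene SNR60, RRT15 and YLR154C-G. FAS2 stood at 1.52 times no-TAP (1.04 to 2.32), PDC1 at 2.29 times (1.14 to 5.38) and YDR524C-B at 3.48 times (1.46 to 10.8). By distinct positions FAS2 lay below 1, at 0.387 (0.152 to 1.17), PDC1 stood at 1.16 (0.285 to 10.2) and YDR524C-B at 1.79 (0.460 to 15.4). AAR2 was at least 7.78-fold higher by tags at the same floor, TRX1 at least 7.54-fold and YJL047C-A at least 6.73-fold, with exact lower bounds of 6.28, 6.08 and 5.42 by tags and of 0.692, 0.835 and 0.492 by positions. RRT15, at 3.49 times (1.58 to 9.60), lies near 5S rRNA gene copies outside the main repeat and is uncertain, with a position ratio of 1.76 (0.568 to 8.81).

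In Lsm1-TAP the leading genes were INO1, the inositol 3-phosphate synthase, EKI1, ethanolamine kinase, NDD1, a cell cycle activator, MIG2, a repressor of glucose-repressed genes, YPL162C, YBR085C-A and the uncertain pair. INO1 stood at 1.64 times no-TAP (1.06 to 2.67), EKI1 at 13.8 times (3.75 to 115), YPL162C at 3.88 times (1.47 to 14.5) and MIG2 at 5.01 times (1.66 to 24.7). By distinct positions INO1 and YPL162C lay below 1, at 0.936 (0.199 to 8.78) and 0.561 (0.0451 to 29.5), EKI1 stood at 2.06 (0.299 to 88.6) and MIG2 at 1.12 (0.136 to 51.7). NDD1 was at least 5.43-fold higher by tags at that floor and YBR085C-A at least 5.01-fold, with exact lower bounds of 4.34 and 3.99 by tags and of 0.172 for both by positions.

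Over all coding genes, 514 lay above no-TAP and 551 below in Xrn1-TAP, 402 above and 534 below in Dcp2-TAP, and 422 above and 593 below in Lsm1-TAP, the 95% interval of the tag ratio excluding 1. Scaled in place of the library totals to the median ratio over the 467 genes with tags in all 4 libraries, which are genes picked for having control tags, 1079 lay above and 455 below, 1128 and 415, and 1362 and 398, so the share above moved from 48.3% to 70.3%, from 42.9% to 73.1% and from 41.6% to 77.4%. Distinct positions, scaled to each library's total of positions, were then compared in place of tags. No gene of the 5684 lay above no-TAP in any of the 3 libraries, RPL9B, NOC4, AHP1, AAR2, TRX1 and EKI1 included. The scaling divides out totals that were 3.90, 9.48 and 5.34 times that of no-TAP in Xrn1-TAP, Dcp2-TAP and Lsm1-TAP. An excess common to all genes is therefore not seen in these ratios. Below no-TAP lay 4, 19 and 33 genes, where binomial draws with no difference gave 5.7, 20.4 and 28.4 on average. At the no-TAP depth and with this scaling, a gene with 0 control positions needed 17 positions in Xrn1-TAP, 37 in Dcp2-TAP or 22 in Lsm1-TAP to be above, a number reached by 3, 5 and 4 genes, so most differences were not detectable at this depth.

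The gene lists differed in the density of upstream positions. Promoters of glycolytic and ribosomal protein genes were dense: the 21 glycolytic and fermentation genes had 4.35 (3.44 to 5.42), 4.75 (4.15 to 5.42), 3.55 (2.82 to 4.42) and 5.21 (3.37 to 7.69) times the positions of the mean gene in Xrn1-TAP, Dcp2-TAP, Lsm1-TAP and no-TAP. The 132 ribosomal protein genes had 2.74 (2.45 to 3.06), 3.12 (2.92 to 3.33), 2.61 (2.35 to 2.89) and 3.22 (2.61 to 3.92) times. By tags 86, 112, 86 and 50 of them were called, that is 65.2%, 84.8%, 65.2% and 37.9% beside 28.5%, 38.6%, 28.5% and 11.2% of all coding genes. With each position counted once, 34, 87, 39 and 4 were called. For both lists the densities lay above all 10000 random lists of the same size in each library. TDH3, the main glyceraldehyde 3-phosphate dehydrogenase, had 11, 34, 10 and 6 positions, PDC1 had 10, 22, 14 and 2, RPL28 had 8, 23, 5 and 2, and RPL9B had 12, 22, 9 and 2. The 8 core histone genes stood at 4.33, 5.16 and 5.01 times in the tagged libraries and at 2.73 times (0.888 to 6.38) in no-TAP, with HTA2 at 5, 20, 2 and 1 positions and HHT2 at 5, 8, 9 and 1. The 28 translation factor genes stood at 2.89, 2.91, 2.06 and 2.03 times, with TEF1 at 8, 19, 8 and 1 positions and YEF3, elongation factor 3, at 7, 17, 8 and 0. The 40 chaperone and stress genes stood at 1.99, 2.30, 2.35 and 2.08 times, with SSA2, a cytosolic Hsp70, at 4, 20, 11 and 3 positions, and the 32 cell wall genes at 1.95, 2.40, 1.75 and 3.01 times, with CIS3 at 3, 17, 2 and 0.

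The 2 biosynthetic lists lay above the mean gene in the tagged libraries. In no-TAP, which had 11 positions in the lipid list and 16 in the amino acid list, the intervals held 1 and also every tagged fold. The 32 ergosterol and lipid genes, led in tags by FAS2 and INO1, stood at 1.66 (1.22 to 2.22), 1.79 (1.49 to 2.12), 2.01 (1.56 to 2.54) and 1.5 (0.751 to 2.69) times the mean gene. FAS2 and INO1 held 11 and 8 of the 46 positions of this list in Xrn1-TAP, 22 and 8 of 129 in Dcp2-TAP, 12 and 10 of 69 in Lsm1-TAP and 6 and 2 of 11 in no-TAP. The 55 amino acid genes stood at 1.58 (1.24 to 1.98), 1.41 (1.21 to 1.64), 1.46 (1.17 to 1.80) and 1.27 (0.728 to 2.07) times. MET6, methionine synthase, had 5, 5, 6 and 0 positions and SHM2, serine hydroxymethyltransferase, had 6, 3, 3 and 3. The glucose-repressed and the sporulation genes lay below the mean gene in each library, though the intervals held 1 in no-TAP and, for sporulation, in Xrn1-TAP. The 21 glucose-repressed and galactose genes stood at 0.330 (0.121 to 0.719), 0.232 (0.116 to 0.416), 0.488 (0.244 to 0.873) and 0.417 (0.0505 to 1.51) times, with ACS1 at 1, 1, 1 and 0 positions and CYB2 at 3, 1, 2 and 1. The 30 sporulation genes, led in tags by SPS1 and SMK1, stood at 0.655 (0.382 to 1.05), 0.488 (0.336 to 0.685), 0.528 (0.308 to 0.846) and 0.438 (0.0902 to 1.28) times. The 37 mRNA decay factor genes stood at 0.687 (0.431 to 1.04), 0.683 (0.518 to 0.885), 0.504 (0.308 to 0.778) and 0.946 (0.408 to 1.86) times, at percentiles 9.33, 5.99, 0.43 and 43.2 of random lists. By tags 16.2%, 37.8%, 8.11% and 10.8% of them were called, beside 28.5%, 38.6%, 28.5% and 11.2% of all coding genes. CDC39 had 1, 4, 2 and 3 positions and PAB1 had 3, 5, 0 and 0. The 36 oxidative phosphorylation genes stood at 1.06 (0.729 to 1.49), 0.727 (0.553 to 0.938), 0.854 (0.588 to 1.2) and 1.09 (0.50 to 2.08) times, the Dcp2-TAP density being at percentile 10.7 of random lists. They were led in tags by QCR6, with 1, 4, 2 and 0 positions, and NDI1, with 2, 1, 1 and 0. The 55 ribosome biogenesis genes, led in tags by NOP14 and PWP2, stood at 0.925 (0.672 to 1.24), 1.2 (1.02 to 1.41), 0.796 (0.585 to 1.06) and 0.955 (0.493 to 1.67) times. By tags 14, 35, 11 and 6 of them were called, and the 63.6% called in Dcp2-TAP, beside 38.6% of all coding genes, lay above all 10000 random lists, while their density there was at percentile 85.0.

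For none of the 13 lists did a tagged library exceed the no-TAP control in its share of upstream positions by more than counting error. The ratio for core histones was 1.58 (0.609 to 5.23), 1.89 (0.780 to 5.94) and 1.83 (0.727 to 5.93), and for translation factors 1.42 (0.780 to 2.80), 1.43 (0.819 to 2.75) and 1.02 (0.553 to 2.01). The cell wall genes in Lsm1-TAP stood at 0.581 times the control (0.351 to 0.994), at percentile 19.9 of matched random lists. Against 10000 random lists matched on mean signal over the 4 libraries, the core histone ratios lay at percentiles 98.3, 99.5 and 99.5 and the translation factor ratios at 99.4, 99.8 and 94.8, while the ribosomal protein ratios, which were 0.852, 0.970 and 0.812, lay at 97.8, 100.0 and 98.4. The chaperone and stress ratios, which were 0.959, 1.1 and 1.13, lay at 87.5, 97.8 and 98.0. At the low end, the mRNA decay factor ratios, which were 0.726, 0.722 and 0.532, lay at 11.0, 7.25 and 1.68. The glucose-repressed ratio in Dcp2-TAP, 0.558, lay at 3.06. The matching also used the no-TAP signal, which is the denominator of these ratios. It can by itself lower the ratios of the random lists, so these percentiles are not read as an excess over no-TAP.

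**Figure D4:**
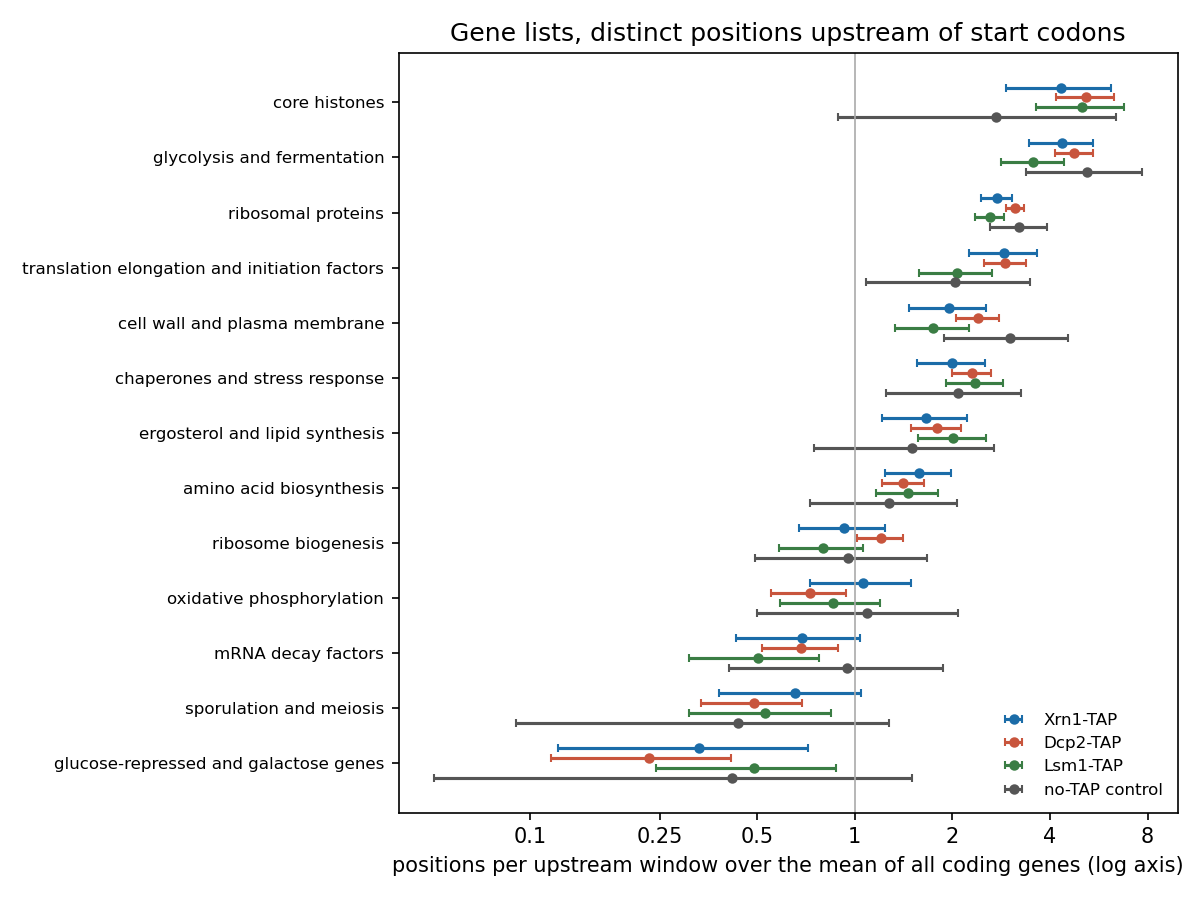
Distinct positions per upstream window relative to the mean of all coding genes (x axis, log scale) for 13 gene lists and 4 libraries; points are the folds and bars exact 95% Poisson intervals, which cover counting error only. Glycolysis lies between 3.55 and 5.21 and glucose-repressed genes between 0.232 and 0.488, and for most lists the no-TAP interval spans the tagged points.

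The last question was whether the 3 factors share promoters. Xrn1-TAP and Dcp2-TAP shared 880 called genes where independent lists would share 626, Xrn1-TAP and Lsm1-TAP 638 where they would share 462, and Dcp2-TAP and Lsm1-TAP 839 where they would share 626, that is 1.41, 1.38 and 1.34 times the independent number. The no-TAP control shared 273, 379 and 268 genes with Xrn1-TAP, Dcp2-TAP and Lsm1-TAP, at 1.5, 1.54 and 1.47 times the independent number. In 1000 circular shifts the tagged pairs shared at most 373, 315 and 417 genes, and the pairs with the control at most 113, 153 and 116. A shift also moves the upstream excess of the shifted library off the windows. The tagged pairs then shared 297, 263 and 356 genes on average, fewer than independent lists would share. The shifts therefore do not test a sharing of genes beyond that excess. With each position counted once, fewer genes were shared but the folds were larger. The tagged libraries then shared 196, 146 and 235 genes, where independent lists would share 28.6, 15.6 and 37.7 (6.84, 9.33 and 6.24 times). With the control they shared 31, 40 and 27, where independent lists would share 2.01, 4.85 and 2.65 (15.4, 8.25 and 10.2 times). The highest fold a pair can reach falls as the longer of its lists grows, so these folds are not on the same scale across pairs. Spearman correlations of upstream tags across genes, which are not independent replicates, were 0.283, 0.210 and 0.245 between tagged libraries and 0.175, 0.206 and 0.158 with the control, and the highest of 1000 circular shifts gave 0.0564 over the 6 pairs. Depth was not made equal for them. The control had a position at 18.2% of genes, beside 47.4%, 75.6% and 54.9% in Xrn1-TAP, Dcp2-TAP and Lsm1-TAP. The lower correlations with the control are therefore not read as less sharing.

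Single positions of tagged and untagged libraries lay near each other more often than under circular shifts. Those shifts move positions off the promoters and small RNA genes, where all 4 libraries had an excess. Nearness beyond that shared excess was therefore not tested. Within 40 bp of an Xrn1-TAP position lay 30.8% of Dcp2-TAP positions (30.4 to 31.3), 28.6% of Lsm1-TAP positions (28.0 to 29.2) and 30.0% of no-TAP positions (28.6 to 31.4), where circular shifts gave 9.46%, 9.46% and 9.48% on average. Within 40 bp of a Dcp2-TAP position lay 47.4% of Xrn1-TAP (46.6 to 48.1), 44.8% of Lsm1-TAP (44.2 to 45.5) and 47.4% of no-TAP positions (45.9 to 48.9), and within 40 bp of an Lsm1-TAP position 34.8% of Xrn1-TAP, 35.0% of Dcp2-TAP and 34.6% of no-TAP positions. Between tagged libraries, 23 genes had a higher share of positions in Dcp2-TAP than in Lsm1-TAP, where binomial draws with no difference gave at most 8, and 9 genes had a lower one, where the draws gave up to 26. The draws split counts by library totals, while upstream windows as a whole held 1.18 times the share in Dcp2-TAP. The excess is therefore not specific evidence for these 23 genes. The numbers for the other 2 pairs did not exceed the highest draw.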

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

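The tests of depth, yield and background placing and the look at chromosome XI were chosen only after the result was seen, although thinning and counting each position once had been fixed earlier as alternatives; the tests of matching positions were chosen before. On chromosome XI, which the gene comparisons leave out, the tallest position of each tagged library was picked, and by tags those of Xrn1-TAP and Dcp2-TAP lay above the no-TAP level. Picking the tallest favours such an excess, and no allowance was made for it. In Xrn1-TAP its tallest position, at index 326600 on the reverse strand, had 47 tags, and in Dcp2-TAP, at index 130489 on the forward strand, 60 tags, and the no-TAP library had 0 tags within 40 bp of either. Within that distance lay 4 and 2 distinct positions, too few to test by positions, since beside 0 control positions 17 and 37 would be needed to lie above no-TAP. The tallest of Lsm1-TAP, 104 tags at index 99827 on the reverse strand, was not above no-TAP by tags either, with 966 CPM within 40 bp beside 838 CPM and a lower bound of the ratio of 0.774.

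The tagged libraries had more distinct positions than the untagged one. Deeper sequencing as the whole cause is argued against, since at equal tags the smallest excess was still 2.53 times. A lower yield of DNA in the untagged pull-down with the same placing, and capture of chromatin through the tag, cannot be told apart, since each strain has 1 library. The upstream shares of Xrn1-TAP, Dcp2-TAP and Lsm1-TAP were 0.957, 1.02 and 0.869 times that of no-TAP, with intervals over 50 kb blocks of 0.907 to 1.01, 0.967 to 1.08 and 0.820 to 0.924. Those intervals hold no variation between libraries, and Dcp2-TAP over Lsm1-TAP alone came to 1.18, so they neither exclude nor favour a difference in yield.

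The excess of positions upstream of start codons was present without a tag, at 1.90 times the genome in the no-TAP library, so a candidate explanation for much of it is background placing that needs no tag, such as easier shearing or pull-down of open chromatin. That share was not exceeded beyond counting error by a tagged library, but 41 to 140 bp upstream the fold of positions over coding in Dcp2-TAP was 1.18 (1.05 to 1.33) times that of no-TAP, beside 1.02 (0.900 to 1.16) in Xrn1-TAP and 0.836 (0.738 to 0.947) in Lsm1-TAP. These intervals are too narrow, since neighbouring positions are taken as independent and a position near several genes counts once for each gene. By tags the order turns, with 3.07 in Dcp2-TAP and 3.32 in no-TAP, and with 1 library each a contribution of the tagged factors at promoters stays open. Tags of the tagged libraries read into the untagged one would put its positions on exactly the same bases, but 3.09% of no-TAP positions (2.60 to 3.65) did so, against at most 2.47% when moved by 5 to 20 bp, so carry-over of a small part is not excluded. Of the tallest positions in the tagged libraries at most 1.30% were found in no-TAP, which also argues against carry-over as the whole cause.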

How the results depend on the processing

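No paired analysis was possible because each strain has 1 library. The direction of the upstream excess was kept in all 4 libraries under each alternative run; numbers of genes moved with depth and with the unit. The TATA alternative was not run, and where ribosomal DNA, mitochondrial DNA and Ty elements were to be left out together, only the ribosomal DNA could be removed. The cause of a moved value was not tested except where thinning sets it. Values are in the order Xrn1-TAP, Dcp2-TAP, Lsm1-TAP, no-TAP. Alternatives chosen after seeing the data were the ratios and overlaps of positions, proximity of positions, thinning of positions, moved start codons, and lists without windows that hold an RNA gene. The tag fold upstream became 1.82, 1.94, 1.65 and 1.90 with each position counted once and 2.07, 2.14, 1.87 and 2.16 without ribosomal DNA. Genes called became 260, 626, 342 and 44 with each position once, 682, 570 and 583 for the tagged libraries thinned to the no-TAP tags, 47, 53 and 34 thinned to its positions, and 389 in no-TAP with 150 bp. Genes above no-TAP became 1079, 1128 and 1362 under median-ratio scaling, which moves all log2 ratios by 0.82, 0.89 and 1.39, and 0, 0 and 0 by distinct positions. With each position once, Xrn1-TAP shared 196 genes with Dcp2-TAP, 146 with Lsm1-TAP and 31 with no-TAP, Dcp2-TAP shared 235 with Lsm1-TAP and 40 with no-TAP, and Lsm1-TAP shared 27 with no-TAP. With 150 bp Xrn1-TAP shared 539 with Dcp2-TAP, 353 with Lsm1-TAP and 136 with no-TAP, and no-TAP shared 214 with Dcp2-TAP and 157 with Lsm1-TAP. Without positions within 100 bp of a no-TAP position, Xrn1-TAP shared 657 genes with Dcp2-TAP and 451 with Lsm1-TAP, and Dcp2-TAP 690 with Lsm1-TAP, at 1.41, 1.35 and 1.38 times independence. The promoter fold over coding became 2.69 in no-TAP with each position once and 2.97 with tandem genes, 2.65 and 2.86 in Xrn1-TAP and Dcp2-TAP with start codons moved by -30 bp, and 2.91 and 2.08 in Dcp2-TAP and Lsm1-TAP with 30 bp.

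With each position once, called members in percent became 25.8, 65.9, 29.5 and 3.03 for ribosomal proteins, 1.82, 14.5, 0 and 0 for ribosome biogenesis, 38.1 for glycolysis in Lsm1-TAP, 0 for histones in no-TAP, 0, 2.70, 0 and 2.70 for mRNA decay, 28.6, 32.1, 25 and 3.57 for translation factors, 20, 45.0, 22.5 and 7.50 for stress, 5.56, 5.56, 0 and 0 for oxidative phosphorylation, 0, 0, 0 and 0 for glucose-repressed genes, 3.33, 3.33, 3.33 and 0 for sporulation, 9.09, 16.4, 5.45 and 1.82 for amino acids, 9.38, 40.6, 9.38 and 9.38 for the cell wall, and 12.5, 37.5 and 3.12 for lipids in Xrn1-TAP, Dcp2-TAP and no-TAP. With 500 bp histones in no-TAP became 12.5. The other 148 values moved by less than counting error or, for counts, by less than 1.5 times. Depth limits the comparison with no-TAP, whose mean window holds 0.229 positions.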

Other observations

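All tests in this part were chosen after the data were seen. Several genes of phospholipid and fatty acid synthesis, picked after their values were seen, had high upstream counts in the tagged libraries. Of these, INO1, ITR1, the main inositol transporter, CDS1, CPT1, EKI1 and FAS2 are known targets of the Ino2-Ino4 activator, which binds the inositol-responsive promoter element. ITR1 had 11, 9, 19 and 6 upstream positions in Xrn1-TAP, Dcp2-TAP, Lsm1-TAP and no-TAP, and EKI1 had 5, 12, 11 and 1. Together the 6 genes held 10.6, 6.88, 12.9 and 16 times the positions of the mean gene.

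Genes of the same pathway that had not been noticed were then looked up. The 12 with a window on the chromosomes used were CHO1, CHO2, OPI3, PSD1, CKI1, EPT1, HNM1, ACC1, ACS2, INO2, OPI1 and PIS1, of which 4 also belong to the ergosterol and lipid list. All but PIS1 are known targets of the activator; PIS1, phosphatidylinositol synthase, is known not to respond to inositol through it and should not have been in the set. The 12 held 1.35, 2.22, 3.73 and 2.55 times the positions of the mean gene in Xrn1-TAP, Dcp2-TAP, Lsm1-TAP and no-TAP. HNM1, the choline transporter, had 1, 10, 5 and 0 positions, CHO1, phosphatidylserine synthase, had 1, 8, 8 and 0, and PSD1, phosphatidylserine decarboxylase, had 2, 3, 9 and 2.

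Over the 4 libraries together these 12 genes lay at percentile 99.24 of 10000 random lists, and the 11 without PIS1 at percentile 99.13, though the 12 lay at percentile 78.1 in Xrn1-TAP alone. The hypothesis that the regulon as a set may carry dense upstream signal is open to a test on other data. Whether it depends on a tag cannot be told apart: the ratios to no-TAP of these 12 were 0.528 (0.200 to 1.55), 0.869 (0.397 to 2.25) and 1.46 (0.657 to 3.83), the highest lower bound being 0.657. Over all 18 genes, where the ratios were computed first, they were 0.628 (0.402 to 1.01), 0.535 (0.358 to 0.825) and 0.962 (0.640 to 1.49). Their upper bounds lie below 1.5, but this cannot count against an excess over no-TAP. Of the 18 genes, 6 had been picked partly for a high no-TAP count, which lowers the ratios, and these 6 held 22 of the 29 no-TAP positions. No technical cause that would single out these promoters was tested.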
